A study of Caenorhabditis elegans with 2 samples.

How the data were processed

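Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Caenorhabditis elegans young adults, 63 hours old per the labels, in 2 biological replicates that form 1 group. The worms carried Y56A3A.18, annotated as znf-593, with an eGFP-containing tag inserted by CRISPR editing at the gene itself, and an antibody against GFP pulled down the tagged protein. Per the labels, the worms were synchronised by bleaching and starvation as L1 larvae, chromatin was sheared by sonication, and the library size range was 200 to 800 bp. A control experiment is named in the labels and was not analysed here, so no background level from untagged worms or input stands beside the values.

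The analysis started from the authors' peak lists. Per the file headers the assembly was ce11, and the lists were filtered or ranked by the irreproducible discovery rate (IDR), which scores how well the rank of a peak is kept between a pair of peak callings. The aligner, peak caller and their versions are not given in the sources used here. The deposited lists comprise 1 ranked and 1 thresholded list per replicate, and 2 ranked and 2 thresholded lists for both replicates together. Peaks were therefore called per replicate and on both replicates together. The list of both replicates that the authors call conservative held 1687 peaks, all of them present in 1 of the ranked lists. Of that list's 84537 distinct entries for the first of its paired inputs, 41654 were found with the same position and signal in the ranked list of replicate 1 and 0 in that of replicate 2. Of the 83464 for the second input, 42200 were found in that of replicate 2 and 0 in that of replicate 1. It is called the conservative list here. Per the file headers, the thresholded lists were derived from 1 further file than the ranked lists, whose role is not stated.

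The signal value of each peak, as deposited by the authors, is a strength of enrichment that is never negative, and its exact scale is not given in the sources used here. The score of each peak in the deposited lists is the authors' scaled IDR rank. The −log10 values in the deposited lists are the authors' significance values, and −log10 of the IDR of at least 2 (IDR of at most 0.01) marked a peak as past the threshold. These are the authors' own values per peak and were used to describe, rank or filter peaks within a list, and the signal values also to compare promoter peaks with other peaks of the same list and to correlate the replicates. The ranked between-replicate list gives 1 signal value per replicate for each peak, and the mean ± SD of those values (n = 2) is given beside the pooled signal of some named peaks. For the other named peaks only the pooled signal is given. The replicates can differ widely there, as at pro-1 (51.3 ± 40.4, SD) and nhr-255 (38.0 ± 22.4). The pooled signal comes from both replicates together and is not the mean of the replicate values. No read counts per library were used, so the depth is unknown here, and intervals on shares cover the counting of peaks only.

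Positions were compared with the Ensembl release 115 annotation of WBcel235, which carries WormBase genes. Every peak ended within the reference chromosome of the same name, with chromosome X at 17718942 bp and the last peak on it ending at 17718912. Coordinates are 1-based. A gene was called bound when a summit lay between 1000 bp upstream and 500 bp downstream of its annotated start, strand considered. The start was the 5' end of the gene model. Mitochondrial genes were left out.

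The comparisons, the gene lists and the rule for named genes were set before the data were examined. The share of summits in the promoter windows of protein-coding genes was set against 1000 random placements of the same number of summits on the same chromosomes, with a two-sided permutation p. The X share was tested with a two-sided exact binomial test against the share of X in the nuclear genome. Each of 22 gene lists, defined by gene symbol, was tested with a two-sided Fisher's exact test against all other protein-coding genes, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. Summits within 200 bp of genes of 10 noncoding biotypes were set against 1000 random placements with the same adjustment. Words of 6 bases, counted with their reverse complement, were compared between windows reaching 50 bp to each side of the summit and windows of the same size 300 bp to each side. The 10 words with the smallest p on chromosomes I, III and V were tested on II, IV and X with Fisher's exact test. The difference of median log2 signal between promoter peaks and other peaks was tested with 100000 permutations, and its interval came from 1000 bootstrap draws. Odds ratio intervals added 0.5 to each count. Agreement of the replicates was measured as the share of overlapping peaks (at least 1 bp, exact binomial 95% interval) and as Spearman and Pearson correlations of log2 signal across peaks, which are not independent replicates.

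Genes named in the text are those at the 20 conservative peaks with the highest signal, up to 4 bound genes with the highest peak signal in each list, the tagged gene and its annotated neighbours, and up to 3 noncoding genes with the highest peak signal per biotype. The lists cover cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis and nucleolus, aminoacyl-tRNA synthetases, translation factors, histones, proteasome, respiratory chain and ATP synthase, chaperones, splicing and snRNP proteins, cuticle collagens, markers of intestine, muscle, neurons, germline and oocytes, sperm genes, transcription factor families, DNA replication and cell cycle, lipid metabolism, detoxification enzymes, immune and lectin genes, and chemoreceptors. Chemoreceptors served as a list with no expected relation to a whole-animal signal.

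The alternatives covered the other thresholded list of both replicates, a stricter signal threshold, each replicate's own thresholded list, other promoter windows, gene assignments, backgrounds, distances, window sizes and definitions of overlap. Alternatives chosen after the values were seen are named as such where they appear. The statistics were tested on simulated data. For the lists, the other summits were placed at random over the genome. For the words, summits and flanks had the same base composition. These runs therefore cannot show false calls from a general preference for promoters or for GC content. In 20 simulations over 19973 genes, a list with 30% of its genes given a summit at the start passed in all 20, and 2 of 420 tests of the other lists passed. In 5 simulations over 1680 summits a planted word was recovered in 5. Besides it, 45 other words were carried forward, and 1 passed, not counting words that largely overlap the planted word. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.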

Results

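The series mapped where in the genome the protein encoded by Y56A3A.18, a C2H2 zinc finger protein annotated as znf-593, was found in whole young adult worms. The 2 biological replicates form 1 group, so the comparisons are between places in the genome and between the replicates, not between conditions. The conservative list held 1687 peaks with a median pooled signal of 71.9 and a median width of 300 bp. Together they covered 481128 bp, or 0.480% of the nuclear genome. The other thresholded list of both replicates held 1826 peaks, of which 1369 were identical to peaks of the conservative list. The replicates' own thresholded lists held 817 peaks for replicate 1 and 754 for replicate 2.

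How far the replicates gave the same peaks was asked first. Of the 817 peaks of replicate 1, 400 overlapped a peak of replicate 2, which is 49.0% (exact binomial 95% interval 45.5 to 52.4%). Of replicate 1's own peaks, 83.6% overlapped the conservative list, and of replicate 2's own peaks 82.5% did. In the other direction, 41.6% of the 1687 conservative peaks overlapped replicate 1's own list and 38.3% replicate 2's. Across the 1687 conservative peaks, the log2 signal values of the replicates correlated with a Spearman rho of 0.37 (95% interval 0.33 to 0.42) and a Pearson r of 0.59. Without the 5% of peaks with the highest mean signal, rho was 0.27. The summits of the replicates lay a median of 30 bp apart, and 86.5% lay within 100 bp of each other. The conservative peaks had been selected by the IDR between these same replicates. The values for that list therefore partly follow from the selection. Over all 94653 ranked peaks, rho was 0.28.

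The strongest peaks lay at ribosomal protein and chaperone genes, at small RNA genes and at places on X without a gene start nearby. The peak with the highest pooled signal, 396.6 (replicate values 178.4 ± 76.9, SD, n = 2), spanned X 11094065 to 11094347, between genes and 2750 bp from W02H3.3. The next, at 388.9 (192.6 ± 63.2), lay on X at 14525756 to 14526062, upstream of nspc-17. The peak upstream of rpl-3, which encodes a protein of the large ribosomal subunit, spanned III 3867477 to 3867664, with a summit 282 bp upstream of the start and a pooled signal of 367.5 (186.7 ± 16.5). Among the 20 strongest peaks, rpl-15 (261.0, a peak shared with K11H12.8 and the snoRNA genes K11H12.12 and K11H12.13), rpl-20 (253.7, a peak shared with Y17G9B.5, which lies nearer) and rpl-35 (248.7) also had a summit upstream of their start. The shared upstream region of F44E5.4 and F44E5.5, which encode Hsp70 family proteins, carried a peak of 325.6 on II at 11759361 to 11759551. The peak upstream of cct-8, a subunit of the cytosolic chaperonin, reached 277.9 and also lay in the windows of Y55F3AR.2 and the noncoding gene Y55F3AR.4.

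Small RNA genes accounted for several of the others. The peak on V at 8500443 to 8500683, inside an intron of pxn-1, lay at the snoRNA gene ZK994.7 and reached 365.8 (184.2 ± 37.6). The start of the tRNA gene WBGene00023221 was also in range, but over 200 bp from the summit. The snoRNA genes C51F7.3 and C51F7.4, inside an intron of frm-7, shared a peak of 311.2. The gene rpr-1, which encodes the RNA of RNase P, lies inside an intron of ints-8 and had its summit 5 bp upstream of its start with a signal of 296.5. T03F7.8 and T03F7.14 shared a peak of 279.4 inside an intron of cutl-18, and the noncoding gene WBGene00195021 had a peak of 274.7. A peak of 292.0 on X at 16056525 to 16056728 lay between genes, with its summit 754 bp from the start of the snoRNA gene T27A8.8. The remaining peaks among the 20 strongest had no annotated gene start in range other than those of piRNA genes. They lay on X at 4209188 to 4209383 (352.9), 6296462 to 6296698 (345.0, in an intron of mom-1), 13700736 to 13700981 (330.4), 11937451 to 11937651 (299.98) and 16682009 to 16682192 (279.3), and on IV at 15895993 to 15896125 (335.0).

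The tagged gene itself was not bound. The gene znf-593 lies on the minus strand of III at 11917836 to 11918719, and the nearest conservative summit was 3097 bp from its start. Its annotated neighbours npp-16 (III 11915928 to 11917873), a nuclear pore gene, and ccf-1 (III 11918828 to 11920237), a deadenylase gene, were not bound either, with the nearest summit 5888 and 1579 bp from their starts.

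Peaks were found at the starts of protein-coding genes more often than random positions. Of the 1687 summits, 702 lay in a promoter window, which is 41.6% (exact 95% interval 39.2 to 44.0%), against 26.0% ± 1.06 (SD) of randomly placed summits. The two-sided permutation p was 0.002, the smallest that 1000 placements can give. Coding exons outside these windows held 9.25% of summits against 17.8% of random positions, and introns 17.7% against 28.5%. Intergenic positions held 26.9% against 24.9%. Promoter peaks were not stronger than other peaks over the whole list. The median log2 signal was 6.17 in both, a difference of 0.00 with a 95% interval of -0.05 to 0.06 (permutation p = 0.989, two-sided). Without the summits near tRNA, snRNA and snoRNA genes, an alternative chosen after the values were seen, promoter peaks were higher by 0.07 (permutation p = 0.011).

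Genes of cytosolic ribosomal proteins, of chaperones and of the respiratory chain and ATP synthase carried peaks at their starts more often than other genes, and chemoreceptor genes less often. In all, 777 of 19973 protein-coding genes were bound, or 3.89%. Of the 22 lists, 6 were bound more often than other genes and 2 less often after adjustment. Of the 82 cytosolic ribosomal protein genes, 25 were bound (30.5%), against 3.78% of other genes, an odds ratio of 11.2 (95% interval 7.04 to 18.1, adjusted Fisher's exact p = 7.8e-15). The strongest were rpl-3, rpl-15, rpl-20 and rpl-35, each with its summit upstream of the start. Of the 60 chaperone genes, 13 were bound (21.7%, odds ratio 6.93, adjusted exact p = 3.0e-06). After cct-8 these were led by hsp-60, the mitochondrial chaperonin (189.7, 94.2 ± 12, SD, n = 2), dnj-19 (172.8, a peak shared with nhr-47, whose start is nearer) and dnj-9 (150.0). With the nearest start only, 16.7% of the chaperone genes were bound (adjusted exact p = 4.8e-04). Of the 65 respiratory chain and ATP synthase genes, 11 were bound (16.9%, odds ratio 5.09, adjusted exact p = 2.1e-04), led by cox-5A (138.9), atp-1, the alpha subunit of ATP synthase (109.8), cox-6A (102.1) and cox-5B (87.2). In the list of replicate 1 alone this share was 6.15% and did not pass (adjusted Fisher's exact p = 0.166).

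The 3 other lists with more bound genes passed by a smaller margin and were lost in several alternatives. Of the aminoacyl-tRNA synthetase genes, 5 of 32 were bound (adjusted exact p = 0.026), with rars-1 (69.8), kars-1 (67.9), gars-1 (66.4) and ears-2 (64.2) in front. Of the splicing and snRNP genes, 7 of 58 were bound (adjusted exact p = 0.026), led by mog-4, a DEAH-box helicase (236.4, 118.7 ± 4.59, SD, n = 2), snr-4 (113.5), lsm-8 (85.6) and prp-19 (76.1). Of the translation factor genes, 4 of 26 were bound (adjusted exact p = 0.047), namely eif-3.C (133.7), iff-2 (93.5), the elongation factor gene eef-2 (85.4) and ife-3 (68.5). Each of these lists missed the threshold in the list of either replicate alone, where the adjusted exact p was 1.00 and 0.328 for the synthetases, 0.582 and 0.594 for splicing, and 0.228 and 0.261 for translation factors.

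Fewer genes than elsewhere were bound among the chemoreceptors, 7 of 1308 (0.535%, odds ratio 0.125, 95% interval 0.0651 to 0.275, adjusted Fisher's exact p = 3.7e-14), with srh-269 (207.0), srh-16 (130.8), sre-23 (108.8) and sri-5 (101.2) the strongest. The chemoreceptors had been set as the list with no expected relation to a whole-animal signal, and they departed strongly from other genes. A departure in these tests therefore does not by itself show a relation to the tagged protein, and its cause was not tested. Among immune and lectin genes 4 of 322 were bound (odds ratio 0.307, adjusted exact p = 0.026), namely clec-126 (88.2), clec-178 (65.7), ilys-5 (60.9) and spp-13 (57.7). That list missed the threshold in the list of either replicate alone (adjusted exact p = 0.304 and 0.496). It also missed the threshold with the other thresholded list (adjusted exact p = 0.165), the nearest start only (0.0997), the window of 500 bp upstream to 200 bp downstream (0.0507) and peaks at or above the median signal (0.0505).

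The other lists did not pass, though 3 of them did under some alternatives. Ribosome biogenesis and nucleolus genes were bound in 5 of 47 cases (odds ratio 2.95, adjusted exact p = 0.077), with larp-1 (157.4), pro-1 (125.0), xrn-2 (96.9) and nol-58 (61.5) in front. Intestine markers were bound in 3 of 18 (adjusted exact p = 0.076), namely the peptide transporter gene pept-1 (84.2) and the vitellogenin genes vit-6 (81.5) and vit-2 (57.8). Over the alternatives the adjusted exact p ranged from 6.3e-04 to 0.428 for ribosome biogenesis genes, which passed with the window from 2000 bp upstream (21.3% bound), with the list of replicate 2 alone (8.51%) and without the summits near tRNA, snRNA and snoRNA genes. For intestine markers it ranged from 0.0021 to 0.471, and they passed with the list of replicate 1 alone (22.2%), with the nearest start only (22.2%), with the window from 2000 bp upstream (22.2%) and without those summits. Germline and oocyte markers were bound in 4 of 37 (syp-4, pgl-3, cgh-1 and oma-2) and muscle markers in 1 of 25 (act-4). None of 25 neuron markers was bound (0 of 25, upper exact 95% limit 13.7%), and none of 89 sperm genes (0 of 89, upper limit 4.06%). The absence among sperm genes depended on the assignment. With the nearest start only, and with the window from 2000 bp upstream, 4.49% of them were bound, and neither setting passed. Mitochondrial ribosomal protein genes were bound in 4 of 67 (mrps-28, mrpl-23, mrpl-32 and mrpl-28), histone genes in 5 of 84 (htz-1, his-37, hcp-3 and his-1 in front), proteasome genes in 2 of 34 (rpn-3 and pbs-5) and DNA replication and cell cycle genes in 4 of 62 (cdc-48.1, pcn-1, cdk-5 and cdk-9). Transcription factor families were bound in 9 of 419, led by nhr-47 (172.8, the peak it shares with dnj-19), ztf-7 (140.0), nhr-255 (82.0) and nhr-48 (70.3). They were bound less often than other genes with the window from 2000 bp upstream (2.63%, adjusted exact p = 0.0185) and with the other thresholded list (1.67%, adjusted exact p = 0.0486), and the adjusted exact p reached 0.580 over the alternatives. Cuticle collagens were bound in 4 of 176 (col-185, col-85, col-106 and col-42), lipid metabolism genes in 3 of 111 (fil-2, fat-3 and dhs-25) and detoxification enzymes in 4 of 185 (gst-27, gst-9, cyp-43A1 and cyp-14A4). The col-42 peak had a pooled signal of 6.82, below its replicate values (37.2 ± 14.8, SD, n = 2).

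**Figure D1:**
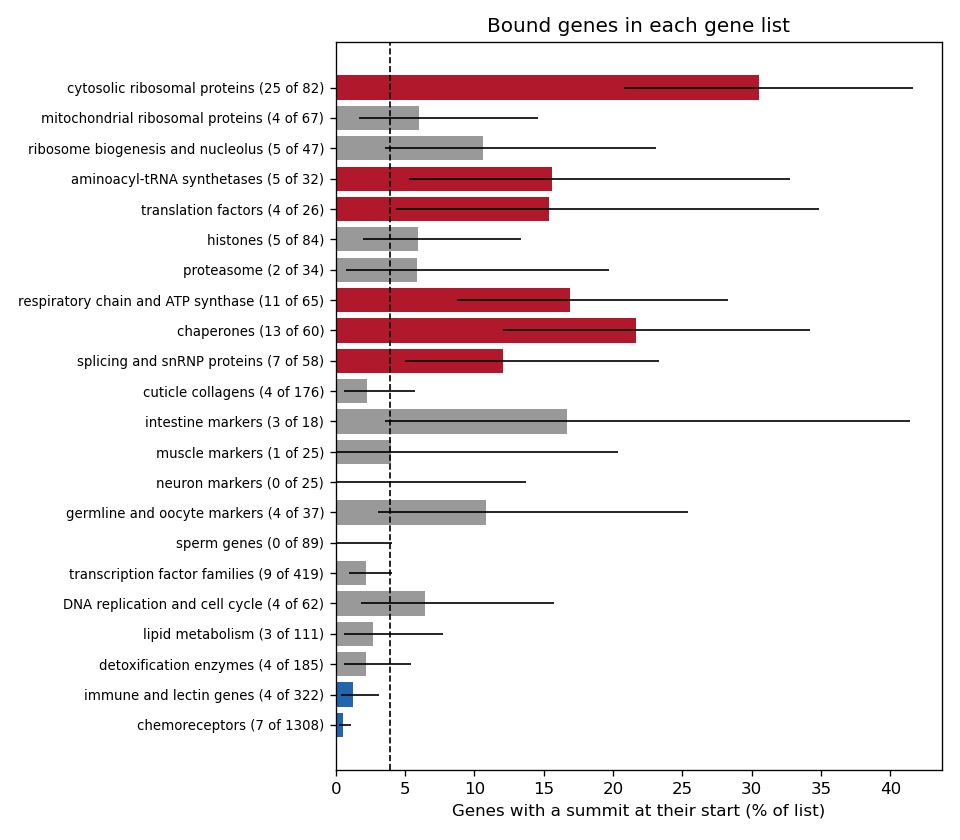
Share of genes in each list with a summit at their start (x axis, percent of the list), with exact binomial 95% intervals, and the number bound in brackets. Red bars lie above and blue bars below other genes after adjustment, grey bars did not pass, and the dashed line marks the 3.89% of all protein-coding genes. Cytosolic ribosomal protein genes reached 30.5% and chemoreceptors 0.535%.

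Transfer RNA genes stood out among the noncoding genes. Within 200 bp of a tRNA gene lay 280 summits, 16.6% of the conservative list, against 4.92 ± 2.17 (SD) of randomly placed summits, a ratio of 57.0. Of the 612 nuclear tRNA genes, 303 (49.5%) had such a summit, and the summits lay a median of 20.5 bp downstream of the gene's 5' end. Close to snRNA genes lay 40 summits (36.3 times the random mean), and 35 of the 129 snRNA genes had a summit. Close to snoRNA genes lay 74 summits (24.5 times), at 71 of 346 genes, and the ratio was 39.1 in the list of replicate 2 alone and 42.1 in that of replicate 1. The snoRNA ratio was lower within 500 bp (15.2) and with peaks that did not pass the threshold as background (17.3). The ncRNA biotype, a mixed class of 7764 genes, had 351 summits (5.82 times). Each of these 4 biotypes gave a permutation p of 0.002, the smallest possible, and an adjusted permutation p of 0.0033. The same held, in the other direction, for piRNA genes (17 summits, 0.325 times) and pseudogenes (24 summits, 0.379 times). Against peaks that did not pass the threshold, in place of random positions, the difference for piRNA genes was lost (0.684 times, adjusted permutation p = 0.165). Genes of rRNA, miRNA, lincRNA and antisense RNA did not pass, with 1, 4, 10 and 4 summits. Within 500 bp, miRNA genes (2.33 times, adjusted permutation p = 0.0325) and lincRNA genes (2.06 times, adjusted permutation p = 0.0314) passed, and miRNA genes also did in the list of replicate 2 alone (4.47 times, adjusted permutation p = 0.0343), but not in that of replicate 1 (adjusted permutation p = 0.779).

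Noncoding genes are named here by the window of 1000 bp upstream to 500 bp downstream of the start. Some therefore lie over 200 bp from the summit, and that summit is not counted for them above. Among tRNA genes, WBGene00023221 ranked first only by this window, as its summit lay over 200 bp away, at the snoRNA gene ZK994.7. Next were WBGene00023110 (X 3036164 to 3036235) and WBGene00023111 (X 3035976 to 3036047). These 2 genes share a peak of 223.1 (101.9 ± 20.5, SD, n = 2). Among snRNA genes the strongest peaks lay at sls-2.1 (224.9), R07E5.16 (214.7) and sls-2.4 (196.2), of which the sls-2 genes encode the SL2 leader RNA that is trans-spliced onto messenger RNAs. Other biotypes had rrn-4.15 (74.6), a 5S rRNA gene, the miRNA genes cel-mir-80 (78.1), cel-mir-238 (73.7) and mir-2214 (71.4), the lincRNA genes M04F3.7 (145.2), linc-44 (107.7) and linc-1 (73.5), and the antisense RNA genes anr-20 (62.8) and anr-36 (55.99). The pseudogenes WBGene00021278 (189.1), WBGene00017287 (122.3) and WBGene00020295 (109.9) also had a summit in their windows, as did the piRNA genes 21ur-10334, 21ur-10800 and 21ur-13102 at the peak of 335.0 on IV.

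**Figure D2:**
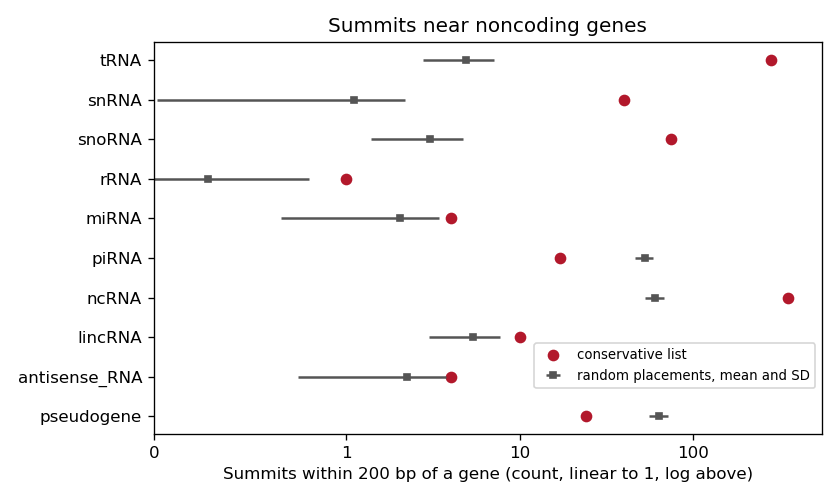
Number of conservative summits within 200 bp of a gene of each noncoding biotype (red circles) and the mean ± SD of 1000 random placements (grey squares). The x axis is a count, linear up to 1 and logarithmic above, and SD bars that would pass below 0 end there. Near tRNA genes lay 280 summits against a random mean of 4.92.

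The X chromosome held more peaks than its length would give. On X lay 354 of the 1687 peaks, or 20.98% (95% interval 19.1 to 23.0%), against 17.7% of the nuclear genome (exact binomial p = 5.0e-04, two-sided). The other chromosomes held 15.4% (I), 14.9% (II), 16.6% (III), 16.2% (IV) and 15.9% (V) of the peaks. Of the 612 tRNA genes, 276 lie on X, and 163 of these had a summit within 200 bp, against 140 of the 336 on autosomes. Without the summits near tRNA genes, an alternative chosen after the values were seen, X held 14.6% of 1407 peaks and lay below its share of the genome (exact binomial p = 0.0026).

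Short sequence words, nearly all of which hold a CG dinucleotide, were enriched at the summits. On the chromosomes used for testing, all 10 words carried forward, each with a CG except ACCACT, were more frequent in the 879 summit windows than in the 1758 flanking windows. The words are not separate findings, as several overlap: AGACGC, GACGCA and ACGCAG are shifted copies of the same run of bases. Flanks were not matched to summits for GC content, so a preference for these words was not separated from base composition. AGACGC was in 10.4% of summit windows and 1.71% of flanks (odds ratio 6.65, 95% interval 4.33 to 9.99, adjusted Fisher's exact p = 3.3e-21). ACCACT was in 14.2% against 2.90% (odds ratio 5.55, adjusted exact p = 5.3e-25) and CGGCCA in 8.19% against 1.08% (odds ratio 8.17, adjusted exact p = 3.0e-19). Of the 204 summit windows with ACCACT over all chromosomes, 114 (55.9%) lay near a tRNA gene, compared with 38.7% of the windows with CGGCCA, 42 of the 175 with AGACGC (24.0%) and 7 of the 154 with GACGCA (4.55%). Many tRNA genes are identical copies, with 402 of them in 32 sets, so windows at such genes are not independent. Copies can also lie on both the chromosomes used to find words and those used to test them. The p-values of ACCACT and CGGCCA may therefore be too small. The other words were ACGCAG (9.10% against 2.10%), GACGCA (8.19% against 1.82%), GCGCCA, ACGCGC, CGCGTC, GCGCGC and CGCGCG, with odds ratios from 3.65 to 5.99. Under the alternatives, 5 to 8 of these 10 words were carried forward again, and ACCACT and CGGCCA were not among them without the summits near tRNA genes. In each alternative all 10 words carried forward there passed, except with the list of replicate 1 alone, where 9 did.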

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

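The test of promoter share in this part was chosen after its value was seen, and the test of repeated sequence before. In the ranked between-replicate list, 110 peaks were past the threshold but are not in the conservative list, a signal in data that the comparisons above do not use. Of these, 8 exceeded the strongest conservative peak, up to a pooled signal of 1577.8 on X at 15810950 to 15811165. Removal at random among the passing peaks is argued against by their promoter share, 0.909% (1 of 110, exact 95% interval 0.0230 to 4.96%) against 41.6% of the conservative list. That interval treats the peaks as independent, though several lie close together, as at 8579505 to 8579804 and 8579705 to 8580004 on IV. A filter on sequence alone could also give a low promoter share, so it does not show that genes played a part. Repeated sequence is a candidate explanation, since the median share of 31-base words around their summits that occur once in the genome was 0.0%, against 100% for the conservative peaks, and 102 of the 110 had under 50% such words, as did 217 conservative peaks. The step by which the authors left them out is not stated: the thresholded lists were derived from 1 further file than the ranked lists, and whether that file lists regions to exclude was not tested, nor was any biological explanation.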

How the results depend on the processing

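Alternatives that leave out summits near small RNA genes, the strongest 100 peaks, neighbouring summits or peaks with a pooled signal below both replicate values were chosen after the values were seen. The promoter share stayed above its background under each alternative (28.7 to 53.9% across windows), and so did the X share except in 1. Without summits near tRNA genes, X held 14.6%, below its share of the genome; this alternative takes out summits at tRNA genes, of which 276 of 612 lie on X. Against 8 lists past the threshold, 5 passed with the other thresholded list (4 of them among the 8) and 4 to 5 with the list of 1 replicate (3 to 4 among the 8). With peaks at or above the median signal 4 passed, with the window of 500 bp upstream to 200 bp downstream 5, and with genes near any ranked peak as background 5, all among the 8. With the nearest start only 6 passed (5 among the 8), and with the window of 2000 bp upstream to 500 bp downstream 11, the 8 included. The cause was not tested. The share of bound aminoacyl-tRNA synthetase genes was 0.0% with peaks at or above the median signal and 0.0 to 6.25% with 1 replicate. Bound genes numbered 439 with peaks at or above the median signal and 369 to 400 with 1 replicate, against 777, as those lists hold fewer peaks. Promoter peaks were stronger than other peaks by 0.069 (log2, permutation p = 0.011) without summits near tRNA, snRNA and snoRNA genes. The overlap of replicates was 44.3% with at least 50% of both peaks and 53.3% as a share of replicate 2's peaks. Spearman's rho was 0.28 over all ranked peaks, 0.27 without the 5% highest and 0.45 in the other ranked list, whose paired values are not the replicates. No paired analysis was possible because there is 1 group.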

Other observations

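The comparisons of families, words, tRNA genes by repeated sequence and strong peaks on X in this part were chosen after the main values were seen, while each test of an explanation was set after its pattern and before its own outcome was seen. Without lists fixed in advance, 175 gene families that share a symbol prefix and have at least 10 genes were tested in the same way. Only the families rpl (14 of 47 bound, adjusted Fisher's exact p = 2.9e-07), rps (11 of 31, adjusted exact p = 1.0e-06) and dnj (6 of 29, adjusted exact p = 0.044) passed, all with more bound genes than elsewhere. These families overlap the lists of cytosolic ribosomal proteins and chaperones and rest on the same peaks, so they are not separate evidence. The rps genes with the highest peak signal, singled out after their values were seen, were rps-1 (179.5), rps-26 (140.6) and rps-19 (125.5). The 10 words found without summits near tRNA genes each hold a CG, led by GACGCA (9.72% against 1.62% of flanks).

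The 280 summits near tRNA genes may involve reads that fit more than 1 gene copy. Equal sharing of reads among identical copies was predicted to leave few sets in which only some copies had a summit. Of 402 tRNA genes in 32 sets of at least 5 identical copies, 98.5% (95% interval 95 to 100%) lay in sets where 20 to 80% of the copies had a summit. This does not decide the question, since copies of similar signal near the threshold can also be split by it. Whether sharing of reads adds summits cannot be told apart from binding. Of the 22 tRNA genes whose 31-base words all occur once, 3 had a summit (13.6%, exact 95% interval 2.91 to 34.9%). That is 12.2 times the random share, with a lower bound of 2.61 times. Of the 590 tRNA genes with repeated words, 300 had a summit (50.8%, 58.3 times the random share), more often than the others (Fisher's exact p = 7.0e-04), which is the direction that sharing of reads would give. A general pull of highly transcribed DNA in any immunoprecipitation was not tested, as no control was analysed here.

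Strong peaks away from gene starts, meaning outside the promoter windows of protein-coding genes and over 200 bp from tRNA, snRNA and snoRNA genes, were concentrated on X. Of the 39 such peaks among the 100 strongest, 20 lay on X (51.3%), 2 of them in the wider windows of noncoding genes (the snoRNA gene T27A8.8, and C18A11.13 with the tRNA gene WBGene00022939), against 113 of 661 weaker peaks away from starts (17.1%), a contrast seen before it was counted. Repeated sequence and GC content are argued against, since the median share of 31-base words that occur once was 100% at these peaks, and matching for GC kept 96.0% of the excess (95% interval 86.4 to 103%). A hypothesis is that these are sites bound by the X-chromosome dosage compensation machinery, whose known 12-base word TCGCGCAGGGAG, with up to 2 mismatches, was in 10 of 20 strong X windows (50%; 8 of 18 without those in wider windows), 0 of 19 strong autosomal windows, 6 of 113 weaker X windows (5.31%), 4 of 548 weaker autosomal windows (0.730%) and 0 of 40 windows flanking the X summits (exact p = 4.4e-04 for strong X against strong autosomal windows). Whether any immunoprecipitation from these worms would give these peaks was not tested, as no control was analysed here.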
